A study of Homo sapiens with 4 samples.

How the data were processed

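Total RNA of Hut78 cells, a cutaneous T-cell lymphoma line, was measured on 4 Affymetrix Human Transcriptome Arrays 2.0, 2 of untreated cells and 2 of cells exposed to ribavirin (50 µM, 120 h). Per the labels' protocols, the cells grew in RPMI medium with 10% serum, RNA came from a Trizol extraction, and 100 ng was amplified and biotin-labelled with a kit made for degraded (fixed) tissue. The labels give no duration for the control, and no date or batch.

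The deposited values are log2 probe set summaries, made by the authors with SST-RMA as the table's own name says. Per the submitters' processing notes, Affymetrix Expression Console and RMA were used, and the series' design text names the Exon Array Computational Tool; versions, background steps and filters are not given in the sources used here. RMA-type processing corrects background, equalises arrays and summarises probes, and changes of genes near the background range can be compressed. What the SST step does to the scale is not given in these sources, so folds may not compare with those of plain RMA. The highest value was 19.9, a ceiling of the scale, so genes near it (9 with a mean above 19) can show little change. A second deposited table held identical values (largest difference 0 over 70523 probe sets), so using it in place of the first tests nothing.

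Of 67528 transcript clusters, 33444 carried 1 gene symbol, 50 several and 34034 none. Clusters with 1 symbol were kept, and where a gene had several (5724 genes) the one with the highest mean over the 4 arrays stood for it, which gave 25847 genes. Control probe sets were left out and dim genes kept. Symbols are those of the table, some old: 22703 were current RefSeq symbols (GRCh38.p14 annotation, used for names only), 1484 were synonyms and 1660 neither. No coordinates were used. As arrays have no depth, signal over background takes its place: the highest background probe set averaged 5.20 in control and 4.95 in ribavirin arrays, and 16121 genes (62.4%) had a control mean at or below the former. Of the changed genes, 486 had both groups in the background range. Among list members named, NEU1, DUSP4, ETV5, STARD4, HDAC9, TNFRSF9 and CADM1 also had control means in that range.

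Ribavirin was compared with control by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariate, 2 residual degrees of freedom and 3.19 prior ones), two-sided, with Benjamini-Hochberg adjusted p under 0.05. Groups came from the sample titles. Array numbers were not treated as pairs, since no label ties same-numbered arrays. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 43 lists with at least 5 members measured, and beside it with the correlation estimated per list and with fry, which asks whether a list's genes move one way and does not compare them with other genes. No list passed with an estimated correlation (smallest adjusted p = 0.379). Of 44 lists written, the mitochondrially encoded one matched no symbol and was not tested. The lists cover interferon, antigen presentation, stress, signalling, death, cell cycle, metabolism, T-cell identity, the drug's targets, other cell types and short RNAs.

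The tests, the alternatives, the lists and the naming rule were fixed before the data were examined. Named were the 12 largest rises and 12 largest falls among genes past the threshold whose ribavirin arrays both lay on one side of both controls (leaving out uncharacterised and noncoding symbols and receptor segments), 6 drug target genes, and up to 4 members with the smallest p in each list. Some genes that this rule picks are not reported here. Alternatives were an intensity trend, robust variance moderation, quantile normalization anew, median centring, leaving out genes below the median, averaging a gene's clusters, the array number as a block, thresholds of 0.1 and 0.01, and each array left out in turn. Leaving out genes with a mean above 19 was added after the data were seen.

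The steps were tested on simulated data for ribavirin against control with all 25847 genes, 200 of them changed, 50 at each fold. limma recovered 0 of 50 at 1.25-fold, 2 at 1.5-fold, 32 at 2-fold and 49 at 4-fold, and called 3 of 25647 unchanged genes. camera found the 1 shifted list and 0 of 37 lists sharing no gene with it. That shifted list had an adjusted p of 0.155 with camera once the correlation was estimated. Genes were simulated as independent, with 1 shifted list in 1 data set. The simulation thus neither measures the power of the estimate nor tests the preset correlation on correlated genes. limma's recovery holds for 200 changed genes, fewer than were called in the data.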

Results

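Hut78 is an established line of malignant T cells from cutaneous T-cell lymphoma. Its transcripts were measured with and without ribavirin, a guanosine analogue used against viruses, to see which genes differ after treatment. There were 2 arrays of untreated cells (control) and 2 arrays of cells kept in ribavirin at 50 µM for 120 h. The values are log2 probe set summaries, and 25847 genes were compared. The gene medians of the 4 arrays lay at 4.24 and 4.30 (control) and 4.20 and 4.21 (ribavirin). The 2 control arrays correlated at Pearson r = 0.998 across genes, the 2 ribavirin arrays at 0.998, and pairs from different groups at 0.990 to 0.991 (genes are not independent replicates). The SD of gene differences was 0.18 between the control arrays, 0.19 between the ribavirin arrays and 0.36 to 0.39 between groups. The number of arrays limits the precision, and since no label says that they came from separate cultures, every p-value measures only the spread between these samples, which may be technical.

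KLHDC7B, a gene with kelch repeats (TC22000430.hg.1), rose with ribavirin from 6.33 ± 0.23 to 12.07 ± 0.19 (SD, n = 2 each), a log2 change of 5.75 (SE 0.15, limma adjusted p = 4.2e-04). PTGS2, the inducible cyclooxygenase (TC01003638.hg.1), rose by 5.72 (SE 0.10) from 5.59 ± 0.14. The guanylate-binding GTPase GBP1 rose 28.7-fold, from 9.53 ± 0.04 to 14.37 ± 0.09. Its relatives GBP5, GBP2 and GBP4 rose by 4.40, 4.21 and 3.70, and the pseudogene GBP1P1, whose probes may cross-hybridise with GBP1, by 3.32. The tryptophanyl-tRNA synthetase WARS rose by 3.48, the G-protein regulator RGS1 by 3.35, the BH3-only gene PMAIP1 by 3.18 and the transcription factor ATF5 by 3.17. GBP2 and GBP1P1 lay within the range of the background probe sets in the control arrays, so their folds are compressed by the floor of the scale.

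SCD, the desaturase that makes monounsaturated fatty acids (TC10000721.hg.1), fell most among the named genes, by 3.48 on the log2 scale (SE 0.10), from 13.63 ± 0.13 to 10.15 ± 0.11 (SD, n = 2 each; limma adjusted p = 4.2e-04). The metalloproteinase inhibitor TIMP2 (-2.96), GIPC3 (-2.49) and the phosphatase DUSP9 (-2.46) fell next. The T-cell surface protein CD5 fell (-2.39), and so did the T-cell transcription factor TCF7 (-2.27), from 14.87 ± 0.08 to 12.60 ± 0.03. FAM101B (-2.17), the kinase SBK1 (-2.15), the protease LGMN (-1.99), SMIM24 (-1.97), the carbonic anhydrase CA6 (-1.96) and the mitochondrial carrier SLC25A23 (-1.83) completed the falls. TIMP2 and SMIM24 reached the background range with ribavirin.

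Over all genes, 3934 changed (limma, Benjamini-Hochberg adjusted p under 0.05), 2413 upward and 1521 downward, or 61.3% upward. With dim genes left out and p adjusted over the 12924 that remained, 3097 rose and 1807 fell. The list counts below are to be read beside the shares of both fits. The fit without dim genes has a looser threshold, as 4904 genes passed it against 3934, while the list counts use the main one. With each array centred on its median the split was 2899 upward and 1034 downward, or 73.7% upward. At least 1.5-fold changes numbered 1909 (1325 up, 584 down), at least 4-fold changes 33 up and 9 down, and an unadjusted p under 0.05 was reached by 7623 genes. In all 3934 both ribavirin arrays lay on the same side of both control arrays, which passing the threshold makes likely in itself. The same held for 59.9% of all genes, against 33.3% if the 4 arrays were interchangeable. An offset shared by the ribavirin arrays, whose gene medians both lay below those of the controls, would also raise that share. The count was 26 without control replicate 1, 27 without control replicate 2, 1185 without ribavirin replicate 1 and 2001 without ribavirin replicate 2, where 1 array of a group is assumed to vary like the other group. The 1.5-fold count was 26, 27 and 1185 in the first 3 of these fits, and at an adjusted p under 0.01 the counts were 1314 and 1252. Of the 24 genes with the largest rises and falls, 12 passed without control replicate 1 (among them KLHDC7B, PTGS2, GBP1, GBP5, GBP2, GBP4, WARS, GBP1P1, SCD, CD5 and TCF7) and 13 without control replicate 2 (the same 12 and SMIM24). All but SMIM24 passed without ribavirin replicate 1, and all 24 without ribavirin replicate 2.

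**Figure D1:**
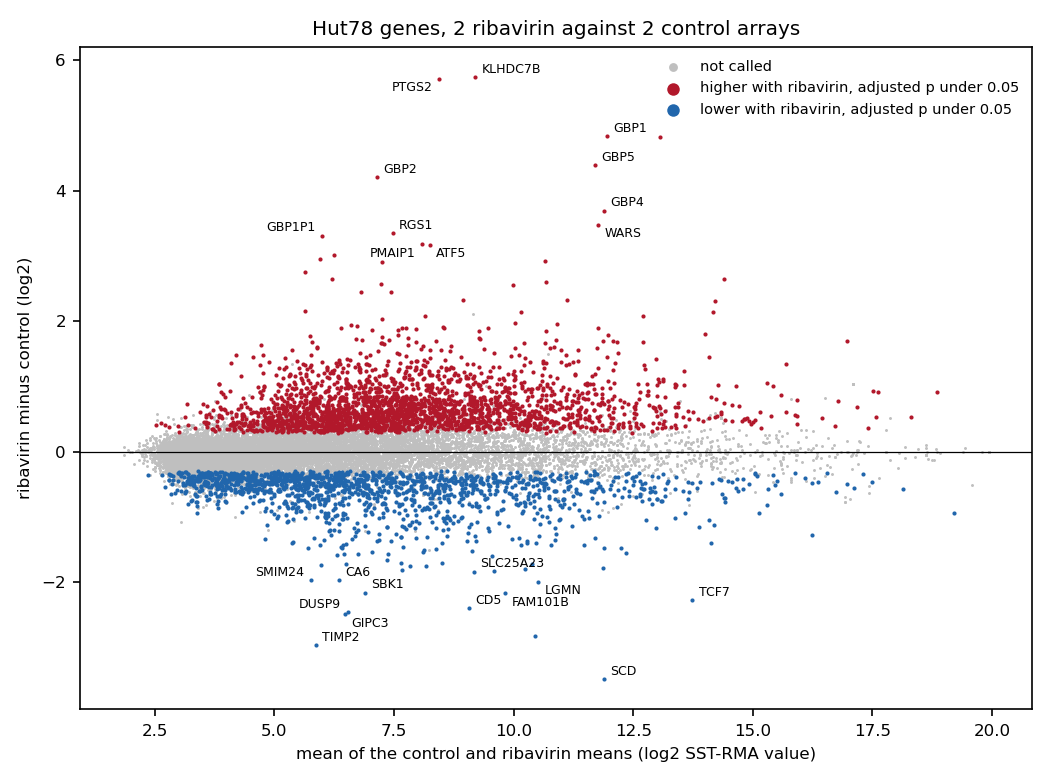
Log2 change (ribavirin minus control) of 25847 genes against the mean of the group means (log2); each point is a gene, red and blue where limma's adjusted p was under 0.05, grey otherwise. KLHDC7B (5.75) and SCD (-3.48) mark the extremes among the labelled genes, which are 11 of the 12 largest rises and the 12 largest falls.

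**Figure D2:**
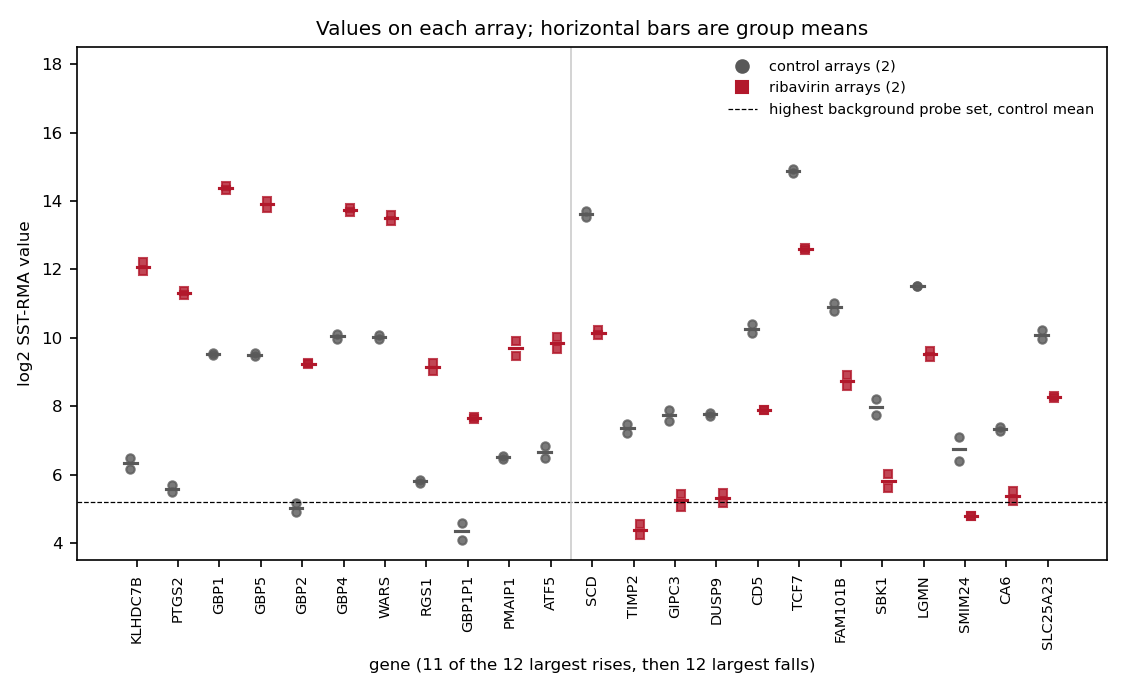
Log2 values of 11 of the 12 largest rises and the 12 largest falls on each of the 4 arrays (grey circles, 2 control; red squares, 2 ribavirin), with bars at the group means and a dashed line at the highest background probe set in the controls. GBP1 went from 9.53 to 14.37; only genes whose groups did not overlap were eligible.

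Of 41 interferon-stimulated genes 17 rose, 5 fell and 19 did not pass (18 rose and 9 fell when adjusted over the list alone). GBP1 (4.85), the chemokine CXCL10 (3.01, control 4.75 within the background range) and PARP9 (1.71) were among those with the smallest p. The 5 that fell, named after their values were seen, were the antiviral genes OASL (-1.03), IFITM1 (-1.02), IFITM3 (-0.87), HERC5 (-0.47) and OAS1 (-0.50, both groups within the background range). Of 24 antigen presentation genes 13 rose, 3 fell and 8 did not pass (14 and 5 adjusted over the list alone). The peptide transporter TAP1 rose by 2.61, the class I light chain B2M by 1.70, HLA-E by 1.59 and TAP2 by 1.69. The class II activator CIITA (-0.84), HLA-DPB1 (-0.45) and HLA-DRB1 (-0.46), likewise named after their values were seen, fell. The interferon list had a median of 0.13 (camera adjusted p = 0.00133; adjusted p = 0.492 with an estimated correlation) and the antigen presentation list of 0.49 (camera adjusted p = 8.5e-05; adjusted p = 0.492 with an estimated correlation). Myeloid markers, which stand for another cell type rich in these genes, had a median of -0.06 (camera adjusted p = 0.535; 1 rose, 0 fell of 20), with 16 of 20 in the background range. The 1 that rose was CD68 (0.64, control within the background range). Without control replicate 1, and also without control replicate 2, 3 interferon genes and 1 antigen presentation gene rose and none fell. The interferon median was 0.06 without ribavirin replicate 1, 0.28 with dim genes left out and 0.21 with quantile normalization. Without ribavirin replicate 1 only 1 antigen presentation gene fell, and without ribavirin replicate 2 the falls were 3 and 1.

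Of 38 genes of the amino acid response under ATF4, 24 rose, 1 fell and 13 did not pass (28 and 1 adjusted over the list alone). WARS (3.48), the alanyl-tRNA synthetase AARS (2.15), the amino acid transporter subunit SLC3A2 (2.65) and the asparagine synthetase ASNS (1.97) had the smallest p, and NUPR1, named after its value was seen, fell by 0.48 within the background range. WARS is also among the genes induced mainly by interferon gamma that are described below, so its rise cannot be assigned to either group. The list's median was 0.93 (camera adjusted p = 7.4e-18; adjusted p = 0.379 with an estimated correlation). In the NRF2 oxidative stress list 13 of 21 rose and 1 fell (13 and 2 adjusted over the list alone), led by the quinone reductase NQO1 (2.14), the cystine transporter SLC7A11 (1.33, control within the background range), ferritin light chain FTL (0.92) and thioredoxin TXN (1.03). The list median was 0.40 (camera adjusted p = 4.7e-05; adjusted p = 0.492 with an estimated correlation). In the unfolded protein response list 6 of 19 rose and 1 fell (7 and 1 adjusted over the list alone), with EDEM1 (1.12), SEL1L (1.34), HERPUD1 (0.88) and DNAJC3 (1.21) among the rises and a median of 0.15 (camera adjusted p = 0.0152; adjusted p = 0.492 with an estimated correlation). In the autophagy and lysosome list 12 of 36 rose and 3 fell (14 and 6 adjusted over the list alone), with MAP1LC3B (1.88), WIPI1 (1.41), NEU1 (1.10) and SQSTM1 (1.10) rising and a median of 0.09 (camera adjusted p = 0.00234; adjusted p = 0.492 with an estimated correlation). Among cytosolic heat shock genes 8 of 18 rose and 3 fell (8 and 5 adjusted over the list alone), HSPA1B by 1.70 and HSPH1 by 1.05, and the co-chaperone FKBP4 fell by 1.32. That list had a median of 0.01 (camera adjusted p = 0.0871, and 0.0214 without control replicate 1; fry adjusted p = 0.0396). Without control replicate 1, and also without control replicate 2, 4 amino acid genes and 1 NRF2 gene rose, none fell and no member of the other 3 lists passed. Without ribavirin replicate 1 there were 7 rises for NRF2, 7 rises and 1 fall for autophagy and 5 and 1 for heat shock, and the amino acid, NRF2 and unfolded protein falls were 0. Without ribavirin replicate 2 autophagy had 1 fall, heat shock 2 and NRF2 0. The unfolded protein median was 0.04 without control replicate 2, and 0.07 without ribavirin replicate 1, without ribavirin replicate 2 and with quantile normalization. The unfolded protein call ended with quantile normalization (adjusted p = 0.291), with dim genes left out (0.330) and without control replicate 2 (0.0949), and the autophagy call with quantile normalization and with dim genes left out (0.156).

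In lists of inflammatory, growth signalling and death genes more members rose than fell, as over all genes, though in most of them the larger part did not pass. Over all genes 2413 of 25847 rose and 1521 fell, and with dim genes left out 3097 of 12924 rose and 1807 fell. The shares of p53 targets and DNA damage genes that rose were close to that of the brighter genes. The share of the brighter genes comes from a fit with p adjusted over fewer genes and a looser threshold, so the comparison is not exact. Of 34 NF-kappaB targets 19 rose and 3 fell (20 and 5 adjusted over the list alone), among them PTGS2 (5.72), CXCL10 (3.01), the adhesion molecule ICAM1 (1.89) and IRF1 (1.52). CXCL10, ICAM1 and IRF1 are also among the genes induced mainly by interferon gamma that are described below, so their rises cannot be assigned to either group. The NF-kappaB median was 0.54 (camera adjusted p = 3.6e-06; adjusted p = 0.492 with an estimated correlation). Of 32 MAPK and immediate-early genes 13 rose and 1 fell (14 and 1 adjusted over the list alone), with the phosphatases DUSP4 (1.78) and DUSP6 (0.92), ETV5 (1.34) and KLF6 (1.96). The members' median was 0.19 (camera adjusted p = 6.9e-05; adjusted p = 0.492 with an estimated correlation). Of 37 BCL2 family, caspase and inhibitor genes 14 rose and 2 fell (19 and 5 adjusted over the list alone), with PMAIP1 (3.18), the death ligand TNFSF10 (2.09), the death receptor FAS (1.29) and BCL2A1 (0.77, control within the background range). Their median was 0.23 (camera adjusted p = 8.5e-05; adjusted p = 0.492 with an estimated correlation). Of 30 p53 targets 7 rose and 0 fell (9 and 1 adjusted over the list alone), with PMAIP1, SESN2 (1.46), FAS and TNFRSF10B (0.57; adjusted p = 0.0516 with clusters averaged) rising and a median of 0.14 (camera adjusted p = 0.00207; adjusted p = 0.492 with an estimated correlation; 0.0684 with dim genes left out). Of 34 DNA damage genes 9 rose and 2 fell (14 and 4 adjusted over the list alone), with the helicase BLM (1.02), TOPBP1 (0.81), BRCA1 (0.75) and NBN (0.77). The median came to 0.23 (camera adjusted p = 9.96e-04; adjusted p = 0.569 with an estimated correlation). Without control replicate 1, and also without control replicate 2, 2 NF-kappaB targets rose, none fell and no member of the other 4 lists passed. The rises without ribavirin replicate 1 were 9, 7, 6, 3 and 4 in the order above, with 1 fall, a MAPK gene. With ribavirin replicate 2 left out p53 targets had 3 rises, the NF-kappaB list 1 fall and the death and damage lists 0 falls. The DNA damage median was 0.15 without ribavirin replicate 1 and 0.14 with quantile normalization, and the MAPK median 0.47 with dim genes left out. The DNA damage call ended with quantile normalization (adjusted p = 0.166), with dim genes left out (0.132) and by fry (0.0949).

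Of 35 mitosis and G2/M genes 16 rose, 3 fell and 16 did not pass (17 and 4 adjusted over the list alone): ANLN rose by 1.09, KIF23 by 0.91, NUSAP1 by 0.78 and KIF2C by 0.63, while CCNB1 (-0.55), PLK1 (-0.56) and CCNF (-0.55), named after their values were seen, fell. The median was 0.27 (camera adjusted p = 3.0e-05; adjusted p = 0.492 with an estimated correlation). Of 69 replication-dependent histone genes none rose, 23 fell and 46 did not pass (0 and 32 adjusted over the list alone), including HIST1H2AB (-1.43), HIST2H4B (-1.31) and HIST1H2AC (-0.85, ribavirin within the background range). Here the median was -0.33 (camera adjusted p = 3.0e-07; adjusted p = 0.492 with an estimated correlation; fry adjusted p = 0.0653). Histone genes are near-identical copies, so probes may be shared. Of 1144 microRNA precursors, listed as a check on RNA size selection, 83 fell and 7 rose (39 and 4 adjusted over the list alone). MIR3143 (-2.82) and MIR3687-1 (-1.82) were among the falls. The count is over a symbol pattern, and its rises include the host gene MIR4435-2HG, which is no precursor. The median log2 change was -0.10 (camera adjusted p = 0.00588; adjusted p = 0.492 with an estimated correlation; fry adjusted p = 0.0945), with 974 in the background range. Their median was -0.20 with dim genes left out (camera adjusted p = 4.52e-09), -0.02 with quantile normalization and -0.03 with arrays centred on their median. In the DNA replication and G1/S list 8 of 37 rose and 3 fell (9 and 4 adjusted over the list alone), RRM2 by 0.81, CLSPN by 1.13 and TYMS by 0.79. The list's median was 0.01 (camera adjusted p = 0.166, and 0.0476 without ribavirin replicate 2). Without control replicate 1, and also without control replicate 2, 1 microRNA fell and no member of the other 3 lists passed. Without ribavirin replicate 1 the counts were 8 mitotic rises, 5 histone falls, 4 G1/S rises, and 22 microRNA falls with 3 rises, and without ribavirin replicate 2 there were 30 microRNA falls, with 0 falls of mitotic and G1/S genes.

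T-cell identity genes fell more often than they rose. Of 34 genes, 18 fell, 7 rose and 9 did not pass (20 and 8 adjusted over the list alone). TCF7 (-2.27), CD5 (-2.39), the homing receptor CCR7 (-1.47) and CD52 (-1.23) had the smallest p, and IL7R, named after its value was seen, rose by 1.74. The median was -0.44 (camera adjusted p = 0.00482; adjusted p = 0.492 with an estimated correlation). Epithelial markers, which belong to another cell type, moved the same way: 6 of 17 fell and none rose (7 and 1 adjusted over the list alone), with ESRP1 (-0.97), KRT8 (-1.36), CLDN7 (-1.22) and MUC1 (-1.17), a median of -0.21 (camera adjusted p = 0.00482; adjusted p = 0.492 with an estimated correlation) and 10 of 17 in the background range. The epithelial median was -0.86 with dim genes left out and -0.11 with quantile normalization. Without control replicate 1, and also without control replicate 2, 2 T-cell genes fell, none rose and no epithelial marker passed. Without ribavirin replicate 1 there were 10 falls and 2 rises of T-cell genes.

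Lipid synthesis and glycolysis genes fell in part. Of 25 cholesterol synthesis and uptake genes 10 fell and 3 rose (12 and 5 adjusted over the list alone): the squalene synthase FDFT1 (-1.02) and DHCR7 (-0.98) fell, and STARD4 rose by 1.20. The median was -0.28 (camera adjusted p = 0.0217; adjusted p = 0.575 with an estimated correlation). Of 18 fatty acid synthesis genes 7 fell and 3 rose (7 and 6 adjusted over the list alone), with SCD (-3.48), the acetyl-CoA carboxylase ACACA (-1.37) and the fatty acid synthase FASN (-1.42) falling and ACSL3 rising by 1.17. The genes' median was -0.11 (camera adjusted p = 0.287, and 0.0427 with quantile normalization; fry adjusted p = 0.0264). Of 34 glycolysis and hypoxia genes 12 fell and 2 rose (15 and 4 adjusted over the list alone), with the aldolase ALDOC (-1.75), GPI (-0.93) and BNIP3 (-0.80) falling and the growth factor VEGFA rising 2.84-fold. The median lay at -0.17 (camera adjusted p = 0.00207; adjusted p = 0.492 with an estimated correlation). Among 86 cytosolic ribosomal protein genes 8 rose, 1 fell and 77 did not pass (8 and 1 adjusted over the list alone), with RPL7 (0.98), RPL37 (0.91), RPL26 (0.87) and RPS27 (0.69). Their median was 0.06 (camera adjusted p = 0.00234; adjusted p = 0.575 with an estimated correlation). The ribosomal median was 0.00523 without control replicate 2 and 0.04 without ribavirin replicate 1, and the glycolysis median -0.27 with quantile normalization and -0.11 with arrays centred. The cholesterol call ended without control replicate 1 (adjusted p = 0.115), without ribavirin replicate 2 (0.0712) and by fry (0.0587), and the ribosomal call with quantile normalization (0.888), dim genes left out (0.392), fry (0.0650) and without control replicate 2 (0.0841). Without control replicate 1, and also without control replicate 2, SCD alone of these lists passed. Falls and rises without ribavirin replicate 1 were 4 and 1 (cholesterol), 5 and 1 (fatty acid), 3 and 1 (glycolysis) and 0 and 4 (ribosome). With ribavirin replicate 2 left out they were 5 and 2, 6 and 3, 6 and 1, and 0 and 5.

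Of 6 genes known as targets, activator or carrier of ribavirin, 3 changed. IMPDH2, an isoform of the dehydrogenase that makes guanine nucleotides, rose from 10.34 ± 0.00 to 11.22 ± 0.07 (SD, n = 2 each; log2 change 0.88, SE 0.07, limma adjusted p = 0.00407), and IMPDH1 measured -0.03 (adjusted p = 0.845). EZH2, the histone methyltransferase, rose by 0.81 (SE 0.10, adjusted p = 0.00839), and the nucleoside transporter SLC29A1 fell by 0.39 (SE 0.07, adjusted p = 0.0234). The cap-binding factor EIF4E measured -0.01 (adjusted p = 0.955) and ADK, the kinase that phosphorylates the drug, -0.25 (adjusted p = 0.0801; 0.0350 with quantile normalization and 0.0385 with dim genes left out). With each array centred on its median the signs of IMPDH1 (0.04) and EIF4E (0.06) turned and SLC29A1 had an adjusted p of 0.0532. None of the 6 passed without control replicate 1 or without control replicate 2. In these fits IMPDH2 had an adjusted p of 0.0631 and 0.0575, EZH2 of 0.0869 and 0.0837 and SLC29A1 of 0.118 and 0.0982. SLC29A1 had 0.113 and 0.101 without ribavirin replicate 1 and without ribavirin replicate 2.

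Around these targets, 6 of 19 mRNAs described as sensitive to EIF4E rose and 2 fell (7 and 2 adjusted over the list alone), with VEGFA (2.84-fold), RRM2 (0.81), HIF1A (1.24) and NBN (0.77) rising and a median of 0.11 (camera adjusted p = 0.0311; adjusted p = 0.492 with an estimated correlation). That call ended with quantile normalization (adjusted p = 0.305), with dim genes left out (0.451) and without control replicate 2 (0.104). In the purine and guanine nucleotide list 5 of 31 rose, 4 fell and 22 did not pass (7 and 6 adjusted over the list alone), led by MTHFD2 (1.80), IMPDH2, PPAT (0.70) and APRT (0.86). The purine median was -0.03, its mean 0.08 and the test pointed up (camera adjusted p = 0.735). Translation initiation factors around EIF4E had 2 rises, EIF4E3 (1.09) and PDCD4 (0.66), and 2 falls among 19 (2 and 3 adjusted over the list alone; camera adjusted p = 0.190; fry adjusted p = 0.0129). Polycomb repressive complex 2 had 3 rises and 2 falls among 11 (3 and 2 adjusted over the list alone; camera adjusted p = 0.507), with EZH2 up and EZH1 (-0.60) down. DNA and histone methylation and deacetylation enzymes had 5 rises and 7 falls among 34 (7 and 11 adjusted over the list alone), including HDAC9 (1.05) and KDM5B (-1.05, ribavirin within the background range). The list median came to 0.06, a mean of -0.02 and a test pointing up (camera adjusted p = 0.773). No member of these 5 lists passed without control replicate 1 or without control replicate 2. Without ribavirin replicate 1, in the order above, rises were 4, 2, 1, 1 and 3 with falls 0, 0, 0, 0 and 2, and without ribavirin replicate 2 rises were 4, 4, 1, 2 and 3 with falls 0, 1, 1, 0 and 3.

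The remaining lists were not called by camera. Rises and falls among members measured were 12 and 7 of 46 for T-cell activation genes (12 and 8 adjusted over the list alone). That list had an adjusted p of 0.470 (median -0.02, mean 0.09, test up) and by fry of 0.0129, with CD44 (1.28), TNFRSF9 (1.40) and IFNG (1.65, control within the background range) rising. Markers described in cutaneous T-cell lymphoma had 6 and 6 of 28 (7 and 9 adjusted over the list alone; adjusted p = 0.769), with ICOS up by 2.33 and CADM1 by 0.98. MYC targets had 4 and 10 of 33 (5 and 12 adjusted over the list alone). The adjusted p for MYC targets was 0.111 (0.00175 with quantile normalization, 0.0310 with dim genes left out and 0.0266 without control replicate 2). STAT3 and STAT5 targets had 6 and 5 of 25 (8 and 5 adjusted over the list alone; adjusted p = 0.497), with PIM2 up by 1.51 and CISH (-1.40, ribavirin within the background range) down. Oxidative phosphorylation genes had 6 and 10 of 87 (10 and 11 adjusted over the list alone; adjusted p = 0.256). Ribosome biogenesis genes had 4 and 3 of 41 (4 and 3 adjusted over the list alone; adjusted p = 0.430; median -0.00, mean 0.07, test up). Splicing factors had 5 and 5 of 35 (6 and 6 adjusted over the list alone; adjusted p = 0.470). Cyclin-dependent kinase inhibitors and D cyclins had 1 and 2 of 13 (2 and 2 adjusted over the list alone; adjusted p = 0.996). Reference genes had 2 and 3 of 15 (3 and 3 adjusted over the list alone; adjusted p = 0.996; median -0.01, mean 0.05, test up), where B2M rose by 1.70.

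Markers of other cell types had 0 rises and 2 falls among 16 B-cell genes (0 and 2 adjusted over the list alone; camera adjusted p = 0.180; fry adjusted p = 0.0304; 0.0434 with dim genes left out), with falls of CD79A (-1.40) and CD79B (-0.64). Fibroblast and endothelial genes had 1 and 2 of 17 (2 and 2 adjusted over the list alone; adjusted p = 0.180), erythroid and megakaryocytic genes 0 and 0 of 17 (0 and 0 adjusted over the list alone; adjusted p = 0.315). T-cell receptor gene segments had 0 and 3 of 43 (0 and 3 adjusted over the list alone; adjusted p = 0.761), TRGV5 (-0.70), TRGV8 (-0.93) and TRGC2 (-0.84), a count over a symbol pattern that also took in TRADD, which is no segment. Small nucleolar RNAs had 21 and 24 of 299 (22 and 25 adjusted over the list alone; adjusted p = 0.965). Small nuclear, Y and vault RNAs had 3 and 11 of 133 (3 and 11 adjusted over the list alone; adjusted p = 0.996; median -0.04, mean 0.06, test up). Those small nuclear RNAs had an adjusted p of 1.3e-04 upward without ribavirin replicate 1, and the small nucleolar RNAs 0.0280 downward without ribavirin replicate 2. Over the 23 lists that camera did not call, 102 of 1020 genes rose and 116 fell. These were 1 and 1 without control replicate 1, 0 and 1 without control replicate 2, 91 and 33 without ribavirin replicate 1 and 64 and 73 without ribavirin replicate 2.

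**Figure D3:**
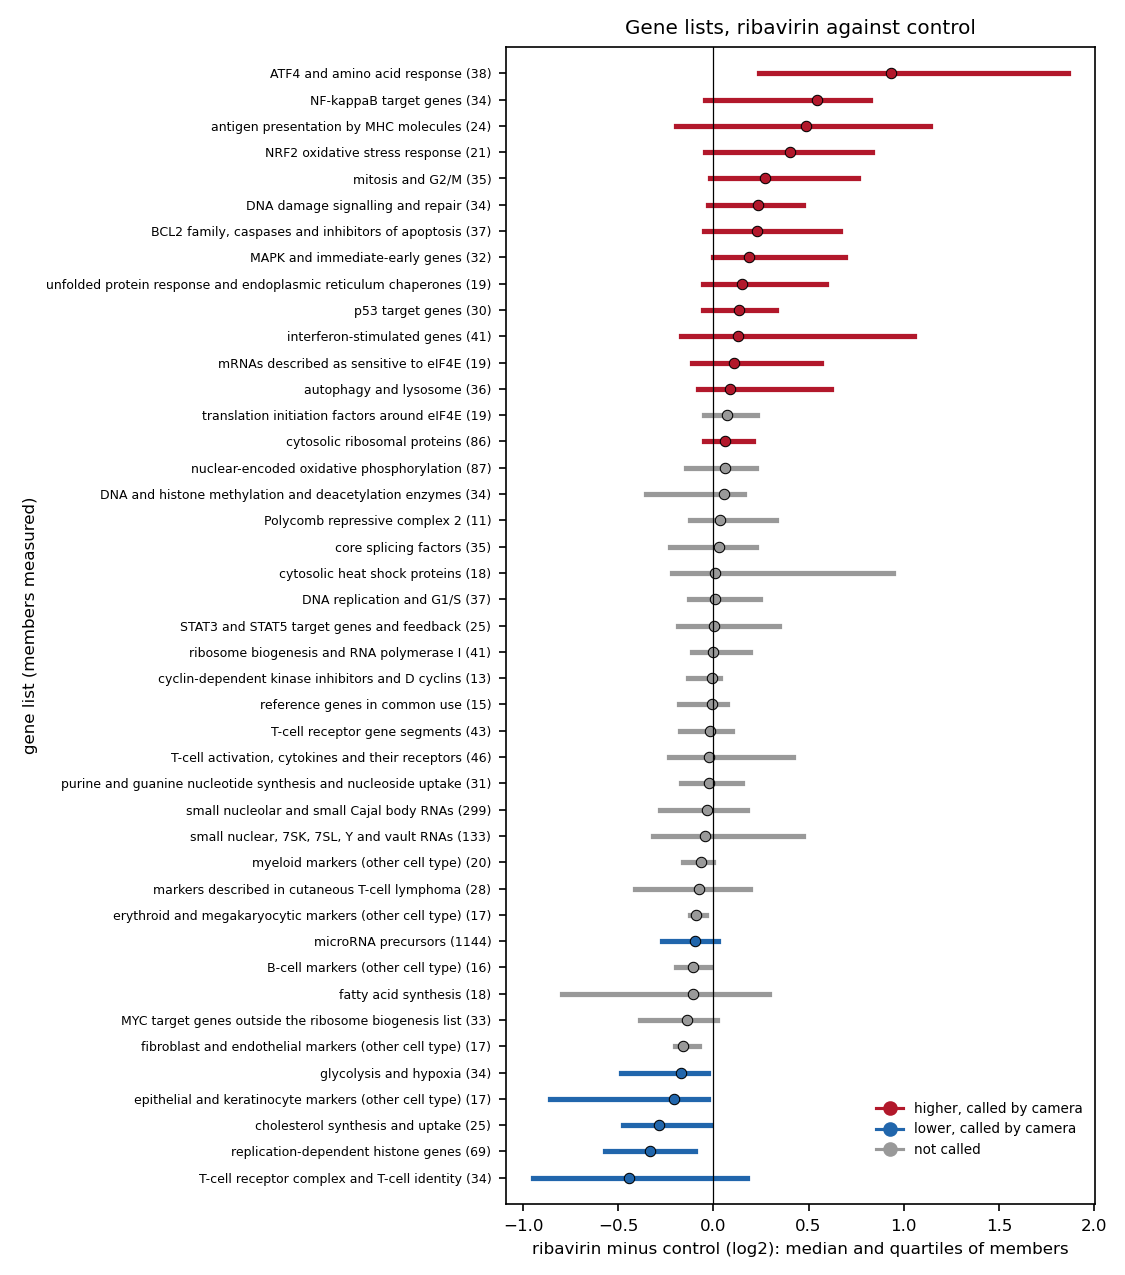
Log2 change (ribavirin minus control) of the members of 43 gene lists, with a point at each list's median and a line from the first to the third quartile; red and blue mark lists that camera called up or down with its preset correlation, none of which passed with an estimated correlation. The ATF4 and amino acid list has the highest median (0.93) and the T-cell identity list the lowest (-0.44).

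Across all 67528 transcript clusters of the array, taken without choosing 1 per gene, 1893 changed, 1199 upward and 694 downward (limma adjusted p under 0.05; 12767 at an unadjusted p under 0.05). With the array number as a block, 7 clusters passed (12230 at an unadjusted p under 0.05). In the main fit, clusters with 1 symbol that is no small RNA held 990 rises and 417 falls among 31740, clusters without a symbol 200 and 244 among 34012, small RNA symbols 9 and 28 among 1704, and clusters with several symbols 0 among 50. Of 22 clusters whose identifiers name chromosome M, the mitochondrial genome, 13 lay above 19, near the scale's ceiling, and the other 9 had a median change of -0.99 (range -1.64 to -0.39), of which 5 passed, all of them falls. The count was 0 without control replicate 1 (11047 at an unadjusted p under 0.05), 0 without control replicate 2 (9535), 1 without ribavirin replicate 1 (9154) and 0 without ribavirin replicate 2 (10361).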

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

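Leaving out genes with a mean above 19 was chosen after the data were seen; all other alternatives were planned. With 1 array left out, which leaves 1 residual degree of freedom, the changed genes ranged from 26 to 2001, those changed at least 1.5-fold from 26 to 1910, drug targets from 0 to 2, lists from 18 to 21 and transcript clusters from 0 to 1. Changed genes were fewest without a control array, and the cause was not tested. At an adjusted p under 0.01, 1314 genes passed, 1252 of them at least 1.5-fold. Changed genes otherwise numbered 3340 to 5691, none of the 3934 turned sign except 4 with clusters averaged, and 20 lists became 0 with an estimated correlation, 17 with quantile normalization and 16 with dim genes left out. With the replicate number as a block (same-numbered deviations correlated at 0.0514), 3340 genes, 20 lists and 7 transcript clusters passed; the block also leaves 1 degree of freedom, and the cause of the last was not tested. The second table moved nothing, as its values are identical. Medians of called lists that moved over 1.5 times were, with dim genes left out, 0.28 (interferon), 0.61 (NRF2), 0.47 (MAPK), -0.86 (epithelial) and -0.20 (microRNA). With quantile normalization they were 0.16 (EIF4E-sensitive mRNAs), 0.21 (interferon), 0.07 (unfolded protein), 0.02 (ribosomal), -0.27 (glycolysis), 0.05 (autophagy), 0.14 (DNA damage), -0.11 (epithelial) and -0.02 (microRNA). With arrays centred they were 0.17 (EIF4E-sensitive mRNAs), 0.12 (ribosomal), -0.11 (glycolysis), 0.15 (autophagy) and -0.03 (microRNA), and with clusters averaged 0.04 (ribosomal). They were 0.04 (unfolded protein) and 0.00523 (ribosomal) without control replicate 2, 0.06 (interferon), 0.07 (unfolded protein), 0.04 (ribosomal) and 0.15 (DNA damage) without ribavirin replicate 1, and 0.07 (unfolded protein) without ribavirin replicate 2. The cause was not tested. Signal over background limits dim genes, whose changes are compressed.

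Directions of lists and drug target genes turned in 50 cases, all of results past no threshold in the main fit, and their cause was not tested. Medians with quantile normalization were -0.0280 (purine), 0.0346 (EIF4E factors), -2.75e-04 (Polycomb), -0.0405 (chromatin enzymes), -0.0280 (G1/S), 0.0740 (kinase inhibitors), -0.0637 (ribosome biogenesis), 0.00896 (oxidative phosphorylation), 0.0265 (STAT targets), -0.0388 (splicing), 0.0319 (myeloid), -0.0245 (small nuclear RNAs) and -0.12 (reference). With dim genes left out they were -0.0198 (purine), 0.0352 (Polycomb), 0.0564 (chromatin enzymes), -0.00381 (ribosome biogenesis), 0.0695 (oxidative phosphorylation), 0.0186 (STAT targets), 0.0272 (splicing), 0.0250 (small nuclear RNAs) and -0.00895 (reference). With median centring they were 0.0595 (kinase inhibitors), 0.0224 (small nuclear RNAs), 0.0375 (IMPDH1) and 0.0565 (EIF4E). With an intensity trend, and again with clusters averaged, they were -0.0422 (small nuclear RNAs) and -0.00895 (reference), and without genes above 19, -0.0785 (reference). By fry they were 0.0564 (chromatin enzymes), 0.0596 (oxidative phosphorylation), -0.0776 (lymphoma markers) and -0.0422 (small nuclear RNAs). With 1 array left out the ranges were -0.00663 to 0.0385 (chromatin enzymes), -0.0450 to -0.0188 (kinase inhibitors), -0.0203 to 0.00384 (reference), -0.0461 to 0.0633 (ribosome biogenesis), -0.12 to 0.0545 (small nuclear RNAs), -0.12 to 0.0217 (small nucleolar RNAs), -0.0316 to 0.0154 (EIF4E) and -0.0682 to 0.0140 (IMPDH1). The ranges of the small nuclear and small nucleolar RNAs each include a fit in which the list passed. Where a median keeps its sign, the direction that turned is the test's.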

Other observations

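The lists in the first 2 paragraphs, and those of interferon classes and class II genes below, were written after the gene results were seen, as were the tests of myeloid, type I, IFNG, class II, glycolysis, unfolded protein, short RNA and G1/S values. All 7 guanylate-binding proteins rose, from GBP6 (0.89) to GBP1 (4.85). Constitutive proteasome subunits rose in 14 of 31 cases and fell in none (21 and 0 adjusted over the list alone), PSMA3 by 1.59 and PSMB6 by 1.09, with a median of 0.33. SAT1, the enzyme that acetylates polyamines for export, rose by 2.44, while 1 of 10 polyamine genes rose in all and OAZ2 (-0.45) and SRM (-0.38) fell.

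Among 20 cytotoxic and natural killer genes 5 fell and 2 rose: NKG7 (-1.75), CTSW (-1.20) and PRF1 (-0.70) fell, while CST7 rose by 1.21 and GZMA by 0.83. Of 16 further epithelial genes 5 fell and none rose, among them RAB25 (-1.72) and SPINT1 (-1.69). Of 17 mitochondrial tRNA synthetases 1 fell, TARS2 (-0.66), and none rose. All 8 spike-in probe sets read lower with ribavirin (median -0.16, range -0.55 to -0.02). None passed limma's threshold, but neither did any of 1343 numbered probe sets, whose changes ran from -3.77 to 4.31, so this says little. The spike-in median was larger in size than those of the called microRNA (-0.10), autophagy (0.09) and ribosomal (0.06) lists. A technical offset between the groups was not tested.

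Interferon-inducible genes rose unevenly: of 26 genes induced mainly by interferon gamma 18 rose and none fell (median 1.51), while of 38 other interferon-stimulated genes 14 rose and 5 fell. The gamma list was written after the gene results were seen and holds GBP1, GBP5, GBP2, GBP4 and WARS, already named as largest rises. The contrast is thus partly fixed by that choice and was not tested. IFNG itself rose by 1.65 (adjusted p = 0.00411, control within the background range), so interferon gamma made by the cells may account for the GTPase and class I part. CIITA and 9 class II genes, set apart after their values were seen, did not share the rise (median -0.24, with 3 falls and no rise). That does not decide whether interferon gamma raised the other genes. A type I response cannot be told apart, since the median of the 38 others, 0.105, spans members going both ways (quartiles -0.20 to 0.60), although the 22 genes induced mainly by type I interferon, a list that omits several that rose, had a median of -0.12 with 3 rises and 4 falls. Hut78 is an established line, and the labels name no other cells in the cultures. The markers themselves cannot check for myeloid cells, since 16 of 20 lie in the background range (median -0.0628, or 0.0319 with quantile normalization). CD68 alone of them rose (0.64, control within the background range).

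The amino acid response may reflect ATF4-driven transcription. Outside the fixed list, 8 cytosolic tRNA synthetases described as ATF4-responsive all rose, against 1 of 8 others, and their medians differed by 0.86; the split was written after the list results but before these 16 values were seen, and genes on the same arrays are not independent. Low oxygen in denser cultures is argued against by the glycolysis and hypoxia median of -0.17, with 12 falls, although VEGFA (2.84-fold) and NDRG1 (0.59) rose, as did HIF1A (1.24). An unfolded protein response cannot be told apart, since its list (median 0.15, 6 rises and 1 fall) lost its call under several settings, although 10 of its chaperones had a median of -0.0136 with 1 rise and no fall. Low glucose was not tested, and what triggers the response stays open.

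Of 69 histone genes 23 fell and none rose (median -0.33), while of 35 mitotic genes 16 rose and 3 fell (0.27; adjusted p = 0.492 with an estimated correlation for both lists). Brightness-dependent scaling is argued against by 10000 lists matched on mean expression, whose medians ran from -0.13 to 0.25, so the histone median stood at percentile 0. Loss of short RNAs without a poly(A) tail cannot be told apart. A set of 238 bright small nucleolar, small nuclear, Y and vault RNAs had a median of 0.0265 (quartiles -0.26 to 0.45). That median ran from -0.06 without ribavirin replicate 2 to 0.18 without ribavirin replicate 1. Of the 238, 24 fell, among them RNY4 (-1.33), and 17 rose. But 90 microRNA precursors of the same brightness had a median of -0.30, with 23 falls and 1 rise. Fewer cells in S phase cannot be told apart either, since the G1/S median of 0.00797 spans members going both ways. Probes shared between histone copies were not tested.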
